A study of Oryza sativa Japonica Group with 30 samples.

How the data were processed

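RNA was measured in root systems of rice seedlings (Oryza sativa, cultivar Nipponbare). Per the labels' protocols, leaves were sprayed with 300 µM piperonylic acid (PA, an inhibitor of cinnamate 4-hydroxylase in the phenylpropanoid pathway) with 0.1% Tween 20, or with a mock solution. The labels' characteristics place the sprays at 7 and 13 days after transplantation, whereas the treatment protocol gives 14 days for the second spray. Some plants were inoculated with the root-knot nematode Meloidogyne graminicola (Mg) at 14 days. Roots were sampled 24 h, 48 h and 96 h after the second spray, and 4 plants were pooled in each sample. The labels give ages of 14, 15 and 17 days after transplantation for these times. Hours given below count from the second spray, not from inoculation. Each of the 10 groups had 3 samples, which gave 30 libraries. Samples were separate pools of plants, so p-values measure the spread between such pools.

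Libraries were made with a QuantSeq 3′ mRNA kit, per the labels' protocols; this kit keeps the strand of the RNA and reads the 3′ ends of transcripts. FastQC 0.11.8, Trimmomatic 0.38, STAR 2.6.1d and DESeq2 are named in the submitters' processing notes. The genome build, the annotation and the strand setting of the counting were not given in the sources used here. The authors deposited a signal per locus, namely read counts divided by library size factors. The 24 h table held 36747 loci in 6 libraries, and the 48 h and 96 h table held 35833 loci in 24 libraries. The 2 tables were normalized separately, and within the second table the 48 h and 96 h columns were on separate scales, so no level was tested across times. In every library 100% of the low values above 0 came out as whole reads, within 0.01 of a whole number, after division by what 1 read was worth in that column. In 3 libraries 1 read was worth close to 1, namely 0.989 and 0.996 in mock + Mg replicates 1 and 2 at 48 h and 1.00 in PA replicate 1 at 96 h. There 0.1%, 52.4% and 26.9% of these values were whole before division, so recovery was less sure in the latter 2. Recovered depth was 1840457 to 3435650 reads at 24 h, 259968 to 369113 at 48 h and 5478644 to 11871480 at 96 h. Both the depth and the loci filled differed at 48 h, where 1564 loci passed the filter.

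Deposited values were tested as log2(normalized count + 1), so fold changes of loci with low counts were understated. Loci with a normalized count of at least 10 in at least 3 libraries were kept. limma 3.58.1 in R 4.3.3 was fitted with an intensity trend and robust variance moderation, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Groups, tests, alternatives, gene lists and the rule for named loci were chosen before the data were examined. The plan set 1 fit over all 24 libraries of 48 h and 96 h. On simulated unchanged and changed loci that fit gave 367 false calls for the 96 h PA comparison (21487 loci), against 10 for a fit of the 96 h libraries of the same draw (20300 loci). It put 15.39% of unchanged loci under an unadjusted p of 0.05, against 4.5% for the fit within 96 h. The comparisons at 48 h and at 96 h were therefore fitted on the 12 libraries of their own time, as a departure from the plan, and the planned fit was kept as an alternative. The averages over both times kept the planned fit, and averages of 96 h alone were added after the data were seen.

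Each step was tested on simulated data in which known loci were changed. For PA at 24 h the fit recovered 30.7% of 2-fold and 91.1% of 4-fold changes (6218 loci, 8 false calls). For PA at 48 h it recovered 68% and 96.9% (1506 loci, 6 false calls), and for PA at 96 h 55.6% and 85.9% (20296 loci, 8 false calls). Interactions were recovered less often than the PA effect of the same time, with 41% and 75.8% at 48 h (1509 loci) and 34% and 84.8% at 96 h (20286 loci). For the PA average over both times, 71% and 97% were recovered with 24 false calls (21487 loci). A list test on the simulated 96 h PA comparison (20296 loci) gave a camera p of 1.4e-18 for a changed set and 0.443 for an unchanged set. Simulated loci varied independently, so this does not show how the list test behaves where members vary together. For the same reason, the recovery and false calls above do not cover deviations that many loci of a library share.

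Loci are named by the IDs in the deposited tables, which do not pair them with gene names. In the RefSeq gene table used here (assembly ASM3414082v1), 1 of 39387 genes named an ID of the tables, so no gene symbols or coordinates are given. The rule for named loci took those with an adjusted p under 0.05 and no overlap between the groups, and of these the 10 with the largest rise and the 10 with the largest fall. For averages the same sign in all 4 single effects replaced the separation (an effect of 0 has no sign), and for interactions the adjusted p alone was used. Because the IDs have no names, at most the first 2 in each direction are printed for a comparison. The rule also took up to 4 members of each list, which are given as counts, and 8 listed loci fixed by ID whatever their result.

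The 11 lists of IDs covered diterpenoid phytoalexins, the phenylpropanoid core, monolignol and lignin, flavonoids, salicylate and pathogenesis-related genes, jasmonate, ethylene, abscisate and dehydration, auxin, the clock and iron acquisition. They held 97 IDs written from general knowledge, so list membership was not checked by ID and a list's theme is as sure as that knowledge. For 53 IDs the RefSeq table had the intended symbol on the chromosome that the ID states. It had the symbol on another chromosome for 3 IDs, which were dropped, and 41 were not looked up or had no entry. A further 2 IDs were not in both tables, which left 92. Another 122 search patterns for product names, which made up 17 further lists including markers of other cell types, were not used because no product text was at hand. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted together over 41 tests, and again with an estimated correlation and with fry. At 96 h the estimated correlation ran from 0.11 for the ethylene list to 0.848 for iron acquisition, above the preset one. The averages of 96 h alone were adjusted over 16 tests.

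Alternatives were other pseudocounts, filters and scalings, the replicate number as a block, library weights, the libraries of a comparison alone, a minimum log2 change of 1, and each library left out in turn. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered whole reads; for PA at 96 h they called 1533 and 1672 loci, against 1421 by limma. Omitting both 96 h inoculated replicates 3 (mock + Mg and PA + Mg), which stood apart in a principal component analysis, was an alternative chosen after the data were seen. With the strand setting not given, a locus and its antisense partner could not be told apart from the tables, and near-identical gene copies could share reads.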

Results

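The data were 3′ mRNA counts from rice roots in 10 groups of 3 libraries. At 24 h after the second spray there were mock and PA groups. At 48 h and 96 h there were mock, PA, mock + Mg and PA + Mg groups. Depth differed widely between times. Recovered reads per library ran from 1840457 to 3435650 at 24 h, from 259968 to 369113 at 48 h and from 5478644 to 11871480 at 96 h. Between 26140 and 29525 loci were above 0 in a 24 h library, 4998 to 6281 in a 48 h library and 24758 to 26329 in a 96 h library. The loci themselves also differed. Loci whose ID number ends in 00 held 98% to 98.1% of the reads at 96 h, but 24.2% to 25.3% at 24 h and 23.1% to 25.2% at 48 h. None of the listed IDs passed the filter at 48 h, and 21 did at 24 h, so gene groups could be described mainly at 96 h. Pearson correlations between replicates of one group were 0.952 to 0.979.

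**Figure D1:**
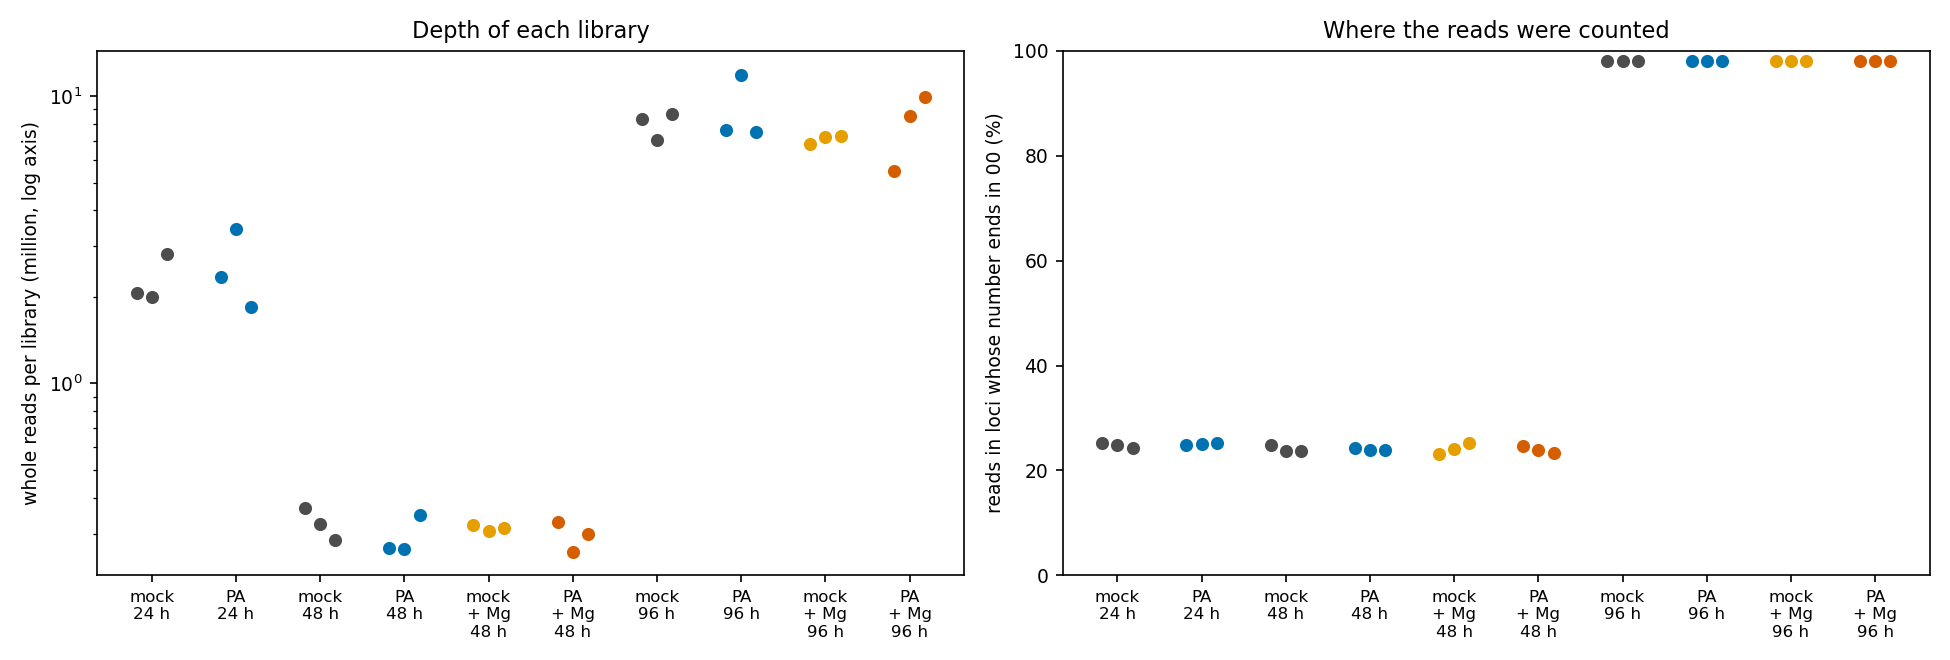
Reads per library (log axis) and percent of reads in loci whose ID number ends in 00, with a point for each of the 30 libraries by time and group. The 48 h libraries hold 259968 to 369113 reads, and the share in such loci is 98% to 98.1% at 96 h but 23.1% to 25.3% at 24 h and 48 h.

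The 24 h comparison asked what the spray did to roots before inoculation. Of 6542 loci 1 rose, Os05g0355450, from 436 ± 123 to 1579 ± 342 normalized counts (SD, n = 3), a log2 fold change of 1.87 ± 0.24 (SE, limma with Benjamini-Hochberg, adjusted p = 0.0115). Across 6529 loci, the level at 24 h ran against that of the same locus at 96 h in the separately normalized table (Spearman rho -0.488), so whether the listed IDs measure their genes at 24 h is open, and their values are given only as such. The 7 tested IDs of the phenylpropanoid core list had a median log2 fold change of 0.03, with 4 values above 0. As a list they did not stand apart from other loci (camera adjusted p = 0.985). No member of any list passed the test over all loci. The single diterpenoid phytoalexin ID tested had a log2 fold change of 2.49 and was the only listed ID under 0.05 when adjusted over the list alone, which for 1 ID is no adjustment. The median was 0.40 for 4 iron acquisition IDs, 0.37 for 2 monolignol IDs, 0.11 for 3 jasmonate IDs and -0.05 for 2 salicylate IDs. Values of the single auxin and clock IDs tested were -0.16 and 0.84. The flavonoid, ethylene and abscisate lists had 0 tested members. At an unadjusted p under 0.05 stood 711 loci (10.87%), and the count of calls was not stable. It was 4 without mock replicate 1, 72 without mock replicate 2, 0 without mock replicate 3 and 12 without PA replicate 2, and Os05g0355450 itself lost the call without mock replicate 3, PA replicate 1 or PA replicate 3, and with TMM factors, quantile scaling or edgeR.

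At 48 h the effect of PA was tested in roots without nematodes. Across 1564 loci, the level at 48 h did not follow that of the same locus at 96 h (Spearman rho -0.135). Which genes the loci measure at 48 h is therefore open, also in the other comparisons of 48 h below. Averaged over inoculation, PA effects of called loci had r = 0.562 with those of the more abundant 96 h locus adjacent by ID number. With those of the same locus at 96 h, r was 0.268. Of 1564 loci, 9 rose and 5 fell (14 in all). Os03g0643800 rose from 3.007 ± 2.62 to 22.42 ± 5.9 normalized counts (SD, n = 3, log2 fold change 2.88 ± 0.53 SE, limma with Benjamini-Hochberg, adjusted p = 0.00231), and Os01g0318202 from 60.69 ± 5.54 to 229.8 ± 70.6 (1.86 ± 0.21, adjusted p = 1.2e-05). Os10g0439862 and Os07g0553450 fell, by log2 fold changes of -1.71 ± 0.40 (adjusted p = 0.0276) and -1.22 ± 0.26 (adjusted p = 0.0116). The count was 4 without mock replicate 1, 24 without mock replicate 2, 7 without mock replicate 3, and 5 without PA replicate 2 or PA replicate 3. Both falls lost their calls without mock replicate 1, mock replicate 3, PA replicate 2 or PA replicate 3, and both rises kept theirs with any of the 6 libraries left out. The joint fit with 96 h ended the calls of Os03g0643800 and Os07g0553450, and DESeq2 and the libraries of the comparison alone that of Os10g0439862.

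In inoculated roots at 48 h the spray changed 113 loci, with 50 higher and 63 lower in PA + Mg than in mock + Mg. Os03g0643800 rose here too, from 1.616 ± 0.539 to 36.21 ± 2.82 normalized counts (SD, n = 3), a log2 fold change of 3.85 ± 0.53 (SE, limma with Benjamini-Hochberg, adjusted p = 1.05e-05), and Os01g0102850 rose by 1.96 ± 0.53 (adjusted p = 0.0166). Os10g0162842 fell from 11.03 ± 5.46 to 1.418 ± 1.57 (-2.44 ± 0.58, adjusted p = 0.00646) and Os01g0783600 from 11.6 ± 4.9 to 1.749 ± 1.72 (-2.35 ± 0.74, adjusted p = 0.0459). The PA effects without and with nematodes, which share no libraries, correlated across 1564 loci at r = 0.314 (jackknife SE 0.066, loci are not independent replicates). Of the 8 loci called in both, 7 moved the same way, where independent lists would share 1. The count was 72 without mock + Mg replicate 2. Os01g0102850 lost its call without mock + Mg replicate 1, PA + Mg replicate 2 or PA + Mg replicate 3, Os10g0162842 without mock + Mg replicate 1, and Os01g0783600 without mock + Mg replicate 2, PA + Mg replicate 1 or PA + Mg replicate 3. The joint fit with 96 h ended the calls of Os01g0102850 and Os01g0783600, and a pseudocount of 0.5 that of Os01g0783600.

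The test of the difference between these PA effects (interaction) called 9 loci at 48 h, 2 with a higher and 7 with a lower effect in inoculated roots. Os04g0180500 went from 74.04 ± 13 in mock to 32.5 ± 3.93 in PA roots without nematodes, and from 38.83 ± 5.3 to 70.73 ± 17.2 normalized counts with them (SD, n = 3, difference 1.98 ± 0.32 on the log2 scale, limma with Benjamini-Hochberg, adjusted p = 0.000586). Os08g0535900 had a difference of 1.19 ± 0.27 (adjusted p = 0.0279). The PA effect was lower in inoculated roots for Os06g0216350 (-2.76 ± 0.58, adjusted p = 0.0165) and Os10g0497750 (-1.45 ± 0.32, adjusted p = 0.0212). In Os08g0535900 mock + Mg stood apart (38.26, against 83.21 in mock, 87.25 in PA and 92.04 in PA + Mg). So it did in Os10g0497750 (76.08, against 38.15, 43.35 and 31.14), but not in Os04g0180500 or Os06g0216350. The interaction shares its mock and mock + Mg libraries with the test of inoculation in mock roots, so calls in both are not independent. Os04g0180500 kept its call without any of the 12 libraries. The other loci named here lost theirs without single libraries of 48 h. All 3 did so without mock + Mg replicate 1, mock + Mg replicate 2 or mock replicate 1, and Os08g0535900 and Os10g0497750 also without PA + Mg replicate 3 or PA replicate 2. So did Os06g0216350 and Os10g0497750 without PA replicate 1, Os08g0535900 without PA replicate 3, and Os10g0497750 without mock replicate 2. The calls of Os08g0535900 and Os10g0497750 were also lost without a filter. The count was 3 without mock + Mg replicate 1 or 2, 19 without mock + Mg replicate 3, 4 without mock replicate 1, 24 without mock replicate 3, and 5 without PA + Mg replicate 3 or PA replicate 3.

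Inoculation alone was tested at 48 h in mock-sprayed roots, where 29 loci rose and 7 fell (36 of 1564). Os04g0571450 rose from 26.89 ± 5.41 to 71.9 ± 9.53 normalized counts (SD, n = 3, log2 fold change 1.40 ± 0.27 SE, limma with Benjamini-Hochberg, adjusted p = 0.00222), and Os01g0584032 from 32.26 ± 9.05 to 83.66 ± 12.8 (1.37 ± 0.25, adjusted p = 0.00145). Os01g0794800 fell by 1.24 ± 0.34 (adjusted p = 0.0439), and Os08g0535900 fell from 83.21 ± 3.88 to 38.26 ± 4.33 (-1.11 ± 0.19, adjusted p = 0.000901). The count was 23 without mock + Mg replicate 1, 15 without mock + Mg replicate 2 and 20 without mock replicate 1, and Os01g0794800 lost its call without mock + Mg replicate 2, mock + Mg replicate 3, mock replicate 1 or mock replicate 2. It also lost the call without a filter, with quantile scaling, library weights or the libraries of the comparison alone, and Os04g0571450 in the joint fit with 96 h. In PA-sprayed roots, limma called 0 loci for inoculation at 48 h, with 114 under an unadjusted p of 0.05 and a smallest adjusted p of 0.0703, and edgeR and DESeq2 on whole reads also called 0. That count was 1 without PA + Mg replicate 1 and 5 without PA + Mg replicate 3. The inoculation effects in mock and PA roots correlated across loci at r = 0.091 (jackknife SE 0.132). Of the 36 loci called in mock roots, 11 (30.6%) had the same sign in PA roots.

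In a principal component analysis of the 96 h libraries, component 1 held 29.1% and component 2 21.5% of the variance. On component 2, PA + Mg replicate 3 (24.6, against -19.3 and -16.5 for replicates 1 and 2) and mock + Mg replicate 3 (48.9, against 1.6 and 18.5) stood apart from their groups. So did mock replicate 1, with 29.4 on component 2 (against 9.4 and 5.1 for replicates 2 and 3) and 13.4 on component 1 (against 43.7 and 39.8). Both inoculated replicates 3 were left out together as an alternative, and mock replicate 1 singly. On component 1, PA + Mg replicates 1, 2 and 3 scored -49.5, -13.8 and -65.7, so that replicate 2 lay farthest from its group there.

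At 96 h the effect of PA on roots without nematodes was tested over 20539 loci, of which 653 rose and 768 fell (1421 in all). Iron acquisition IDs were lower after PA. All 5 had values below 0 with a median log2 fold change of -1.67, and 2 of them fell (4 when adjusted over the list alone). Mock values spread widely, from 7251 ± 1920 for Os03g0667500 to 5575 ± 4880 for Os03g0307200 (SD, n = 3), and Os03g0237100 overlapped between the groups. The list ranked below other loci (camera adjusted p = 7e-05, adjusted p = 0.527 with an estimated correlation). In the phenylpropanoid core 3 of 13 IDs fell (5 adjusted over the list alone) and 11 values were below 0, with a median of -0.39 (camera adjusted p = 0.00288, adjusted p = 0.527 with an estimated correlation). Of the 11 salicylate and pathogenesis-related IDs, 2 fell (7 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 0.0142, adjusted p = 0.527 with an estimated correlation). Of the 7 monolignol and lignin IDs, 2 fell (3 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.0344, adjusted p = 0.527 with an estimated correlation). All 7 clock IDs had values above 0 with a median of 0.14, and 1 rose (1 adjusted over the list alone, camera adjusted p = 0.0266, adjusted p = 0.527 with an estimated correlation).

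The other lists did not pass the list test for PA at 96 h. Of 15 diterpenoid phytoalexin IDs, 2 fell (2 adjusted over the list alone) and 11 values were below 0, with a median of -0.26 (camera adjusted p = 0.0804). Of 7 jasmonate IDs 1 rose, and adjusted over the list alone 1 rose and 2 fell (median -0.17, camera adjusted p = 0.425). Of 5 ethylene IDs 1 fell, and adjusted over the list alone 1 rose and 1 fell (median 0.42, camera adjusted p = 0.585). Among lists too short for the test, 2 of 4 abscisate and dehydration IDs fell (2 adjusted over the list alone), 0 of 3 auxin IDs passed with a median of -0.24 (0 adjusted over the list alone), and the single flavonoid ID had a value of -0.81 without passing (0 adjusted over the list alone). The 8 loci fixed by ID also did not pass. Their values ran from -0.59 ± 0.19 for Os05g0322900 (1022 ± 18.2 in mock and 682.5 ± 103 in PA, limma with Benjamini-Hochberg, adjusted p = 0.0888) to 0.03 ± 0.11 for Os02g0626100 (adjusted p = 0.909).

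The largest rises by the rule for PA at 96 h were Os07g0418700, from 18.07 ± 11.4 to 148.5 ± 34.9 normalized counts (SD, n = 3, log2 fold change 3.17 ± 0.76 SE, limma with Benjamini-Hochberg, adjusted p = 0.0357), and Os06g0559400, from 18.11 ± 7.65 to 126.9 ± 26.6 (2.79 ± 0.29, adjusted p = 4.5e-05). Os11g0454200 fell from 36.78 ± 35.6 to 1.101 ± 1.03 (-3.81 ± 0.71, adjusted p = 0.00638) and Os10g0507700 from 31.64 ± 7.93 to 2.754 ± 2.57 (-3.44 ± 0.70, adjusted p = 0.00603). Of the 1421 loci, 349 changed by a log2 fold change of at least 1. The count was 766 without mock replicate 2, 589 without PA replicate 1 and 885 without PA replicate 2. Os07g0418700 kept its call only without mock replicate 1, and lost it without mock replicate 2, mock replicate 3 or any of the 3 PA libraries.

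**Figure D2:**
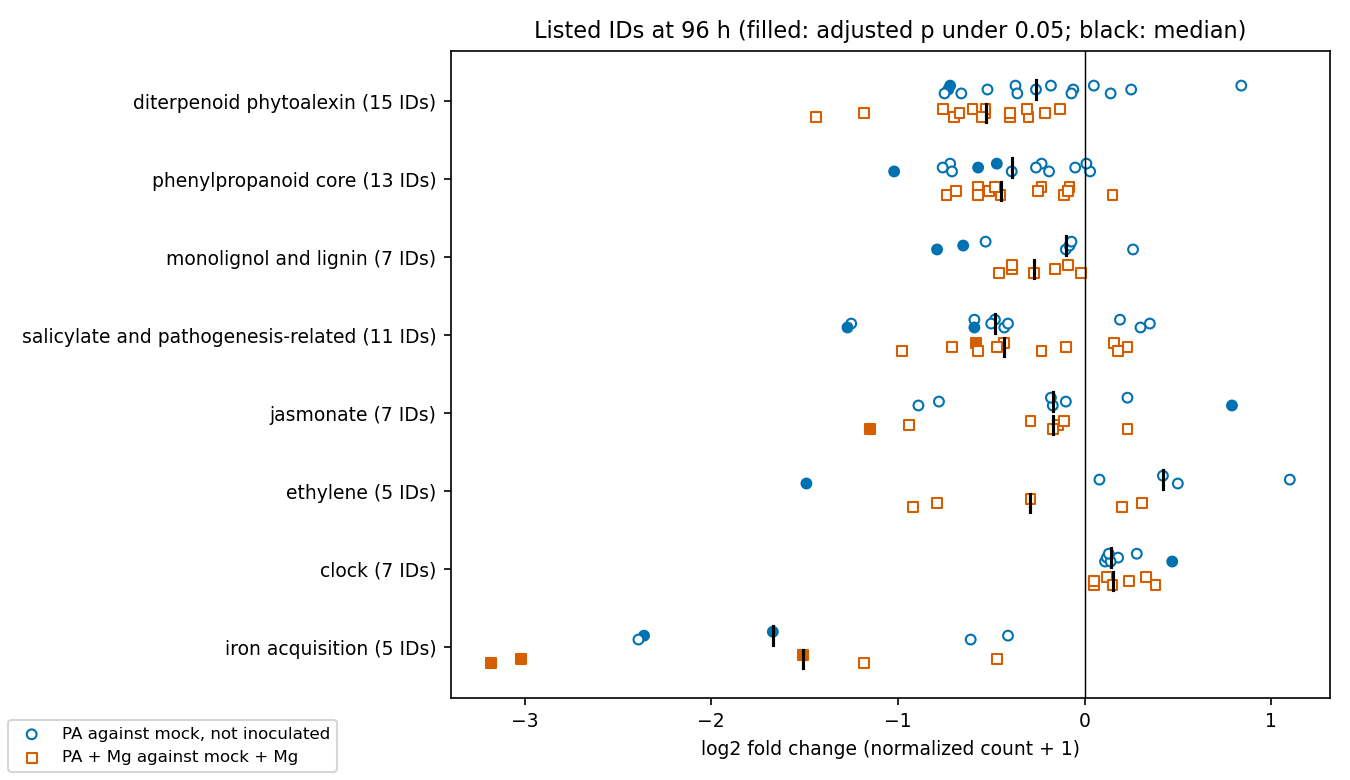
Log2 fold change of listed IDs at 96 h, by list, on the normalized count + 1 scale. Only lists with at least 5 tested members are shown. PA is set against mock without (circles) and with (squares) nematodes. Filled symbols passed the test, small vertical offsets only separate points, and black bars are medians. Iron acquisition medians lie at -1.67 and -1.51, and clock medians at 0.14 and 0.15.

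With nematodes, PA changed 570 loci at 96 h (305 rose and 265 fell). All 5 iron acquisition IDs again had values below 0, with a median of -1.51, and 3 fell (5 adjusted over the list alone, camera adjusted p = 1.73e-07, adjusted p = 0.527 with an estimated correlation). All 15 diterpenoid phytoalexin IDs, rice defence compounds made in response to infection, had values below 0 with a median of -0.53. None passed over all loci and 5 fell when adjusted over the list alone (camera adjusted p = 8.61e-05, adjusted p = 0.527 with an estimated correlation). Lower medians with a list call were also found for the phenylpropanoid core (-0.45, 0 of 13 passed, 1 lower adjusted over the list alone, camera adjusted p = 0.00793), salicylate (-0.43, 1 of 11 fell, 3 adjusted over the list alone, 0.0266), monolignol and lignin (-0.27, 0 of 7 passed, 2 lower adjusted over the list alone, 0.0294) and jasmonate (-0.17, 1 of 7 fell, 2 adjusted over the list alone, 0.0294). The 7 clock IDs were all above 0 with a median of 0.15 (0 passed, 2 higher adjusted over the list alone, camera adjusted p = 0.0193). For these 5 lists the adjusted p was 0.527 with an estimated correlation.

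The ethylene list was not called in that comparison (median -0.29, 0 passed, 1 lower adjusted over the list alone, camera adjusted p = 0.236). Of 4 abscisate and dehydration IDs 1 rose and 1 fell (1 and 1 adjusted over the list alone), 0 of 3 auxin IDs passed (0 adjusted over the list alone, median -0.30), and the single flavonoid ID did not pass over all loci (its count of 1 lower adjusted over the list alone rests on an unadjusted p of 0.0404). By the rule, Os09g0471000 rose from 4.092 ± 2.23 to 22.59 ± 5.72 normalized counts (SD, n = 3, log2 fold change 2.27 ± 0.45 SE, limma with Benjamini-Hochberg, adjusted p = 0.0109) and Os07g0638400 from 267.2 ± 8.85 to 1129 ± 357 (2.03 ± 0.32, adjusted p = 0.0118). Os11g0262600 fell from 182.8 ± 71.1 to 9.882 ± 5.03 (-4.11 ± 0.83, adjusted p = 0.0369) and, of the loci fixed by ID, Os12g0555500 fell from 7292 ± 805 to 4900 ± 741 (-0.58 ± 0.15, adjusted p = 0.0465). The count was 269 without mock + Mg replicate 2 and 243 without PA + Mg replicate 1, and it was 345 without both inoculated replicates 3 (mock + Mg and PA + Mg). Os11g0262600 lost its call without any 1 of the 6 libraries, Os12g0555500 without any but PA + Mg replicate 1, and Os09g0471000 without PA + Mg replicate 1. Without both inoculated replicates 3, Os07g0638400 (2.22, adjusted p = 0.0528), Os11g0262600 and Os12g0555500 lost their calls. Os11g0262600 also did so with edgeR, and Os12g0555500 without a filter or with library weights.

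PA effects with and without nematodes at 96 h ran in the same direction for 69% of the 20539 loci (r = 0.521 across loci, jackknife SE 0.141). All 376 loci called in both moved the same way, where independent lists would share 39.4. The test of their difference called 0 loci with limma, with 1021 (4.97%) under an unadjusted p of 0.05 and a smallest adjusted p of 0.177, and edgeR called 0 and DESeq2 9. That count was 1 without mock replicate 3 or PA + Mg replicate 2 and 2 without PA + Mg replicate 1. No listed ID passed that test. Among the lists only the diterpenoid phytoalexins were called, as a set, with 12 of 15 differences below 0 and a median of -0.33 (0 passed when adjusted over the list alone, camera adjusted p = 0.03), and the call was lost with an estimated correlation (adjusted p = 0.616 with an estimated correlation). Differences were not called for the ethylene list (camera adjusted p = 0.0803), jasmonate (0.145, 1 lower adjusted over the list alone), iron acquisition (0.214), the phenylpropanoid core (0.425), salicylate (0.464), monolignol and lignin (0.627) or the clock (0.985), and 0 members of any list passed over all loci.

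**Figure D3:**
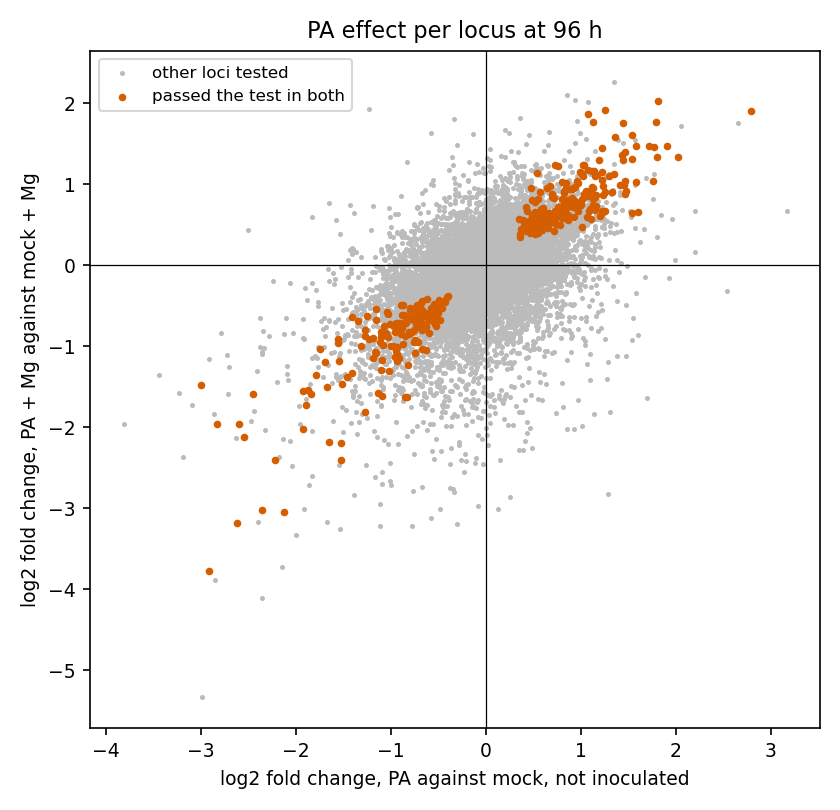
Log2 fold change of PA against mock at 96 h for each tested locus, without nematodes on the horizontal axis and with nematodes on the vertical axis, with the loci that passed both tests coloured. The 376 coloured loci all lie in the quadrants of equal direction, and r across the 20539 loci is 0.521.

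Inoculation of mock-sprayed roots changed 55 loci at 96 h, of which 40 rose and 15 fell. The 5 iron acquisition IDs all had values above 0 with a median of 0.74 (0 passed, 2 higher adjusted over the list alone, camera adjusted p = 0.00034, adjusted p = 0.527 with an estimated correlation). All 5 overlapped between the groups. Mock values spread widely, from 7251 ± 1920 for Os03g0667500 to 5575 ± 4880 for Os03g0307200 (SD, n = 3). The estimated correlation of 0.848 makes the 5 IDs far from independent. All 13 phenylpropanoid core IDs lay above 0 with a median of 0.16 (0 passed, 0 adjusted over the list alone, camera adjusted p = 0.0221, adjusted p = 0.57 with an estimated correlation), as did all 7 jasmonate IDs with a median of 0.15 (0 passed, 1 higher adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.527 with an estimated correlation). Not called were salicylate (median 0.18, 2 higher adjusted over the list alone, camera adjusted p = 0.0538), monolignol and lignin (0.09, 0.0704), the clock (-0.03, 0.513), ethylene (-0.16, 0.758) and the diterpenoid phytoalexins (-0.01, 0.985). In shorter lists the medians were -0.06 for abscisate (1 of 4 lower adjusted over the list alone) and -0.23 for auxin, and the flavonoid ID had a value of -0.92. No listed ID passed over all loci, and none beyond those given here passed when adjusted over the list alone.

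By the rule, Os11g0623800 rose after inoculation of mock-sprayed roots at 96 h, from 3.03 ± 1.88 to 19.48 ± 0.253 normalized counts (SD, n = 3, log2 fold change 2.48 ± 0.46 SE, limma with Benjamini-Hochberg, adjusted p = 0.0319), and Os08g0178500 from 2.946 ± 0.344 to 16.07 ± 2.45 (2.11 ± 0.37, adjusted p = 0.0216). Os02g0757100 fell from 617.6 ± 54.3 to 129 ± 46.3 (-2.30 ± 0.33, adjusted p = 0.0216) and Os02g0767800 from 94.87 ± 17.3 to 28.19 ± 6.23 (-1.72 ± 0.33, adjusted p = 0.037). The count was 36, 8 and 20 without mock + Mg replicate 1, 2 and 3, and 115, 4 and 2 without mock replicate 1, 2 and 3. Os11g0623800, Os08g0178500 and Os02g0767800 kept their calls only without mock replicate 1 among the 6 libraries, and Os02g0757100 only without mock replicate 1 or mock + Mg replicate 3. Without both inoculated replicates 3, the count was 29, and a fit of the 6 libraries of the comparison alone gave 12. In both of these fits the calls of Os11g0623800 and Os08g0178500 were lost, and Os02g0767800 lost its call without a filter or with a filter of 50.

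In PA-sprayed roots inoculation changed 86 loci at 96 h, of which 62 rose and 24 fell. All 13 phenylpropanoid core IDs had values above 0 with a median of 0.30 (1 higher adjusted over the list alone, camera adjusted p = 0.00559, adjusted p = 0.527 with an estimated correlation). Salicylate IDs (median 0.30, 9 of 11 above 0, 1 higher adjusted over the list alone, camera adjusted p = 0.0199) and monolignol and lignin IDs (0.20, 6 of 7 above 0, 0.0406) also ranked higher, both with an adjusted p = 0.527 with an estimated correlation. Diterpenoid phytoalexin IDs ranked lower (median -0.46, 11 of 15 below 0, 2 lower adjusted over the list alone, camera adjusted p = 0.0266, adjusted p = 0.599 with an estimated correlation), as did ethylene IDs (-0.46, 4 of 5 below 0, camera adjusted p = 0.036, adjusted p = 0.527 with an estimated correlation). Not called were iron acquisition (0.18, 2 higher adjusted over the list alone, 0.0804), jasmonate (-0.02, 0.585) and the clock (-0.04, 0.585). Medians of the shorter lists were 0.11 for abscisate (2 higher adjusted over the list alone) and -0.11 for auxin (1 lower adjusted over the list alone), and the flavonoid ID had -1.11 (1 lower adjusted over the list alone, which for 1 ID is no adjustment). No listed ID passed over all loci, and none beyond those given here passed when adjusted over the list alone.

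For inoculation of PA-sprayed roots at 96 h, Os02g0131400 rose from 16.7 ± 1.48 to 54.27 ± 3.66 normalized counts (SD, n = 3, log2 fold change 1.64 ± 0.30 SE, limma with Benjamini-Hochberg, adjusted p = 0.0258) and Os12g0555100 from 215.1 ± 20.1 to 582 ± 147 (1.41 ± 0.18, adjusted p = 0.0087). Os11g0661600 fell from 13.22 ± 6.17 to 0.6054 ± 1.05 (-3.21 ± 0.60, adjusted p = 0.0291) and Os10g0471100 from 54.04 ± 33.2 to 6.556 ± 3.83 (-2.85 ± 0.49, adjusted p = 0.0194). The count was 340 without PA + Mg replicate 2, 8 without PA + Mg replicate 3, and 18, 9 and 28 without PA replicate 1, 2 and 3, and it was 37 without both inoculated replicates 3. Os02g0131400 kept its call only without PA + Mg replicate 2, Os11g0661600 only without PA + Mg replicate 2 or PA replicate 3, Os10g0471100 lost it without PA + Mg replicate 3, PA replicate 1 or PA replicate 2, and Os12g0555100 without PA replicate 2. Without both inoculated replicates 3, Os11g0661600 and Os10g0471100 lost their calls, the former also with quantile scaling. Inoculation effects with and without PA correlated across loci at r = 0.381 (jackknife SE 0.241), and all 11 loci called in both moved the same way.

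Averaged over inoculation and both times, PA changed 1513 of 21753 loci, with 712 higher and 801 lower. Of these calls, 1090 were of loci at 0 in all 48 h libraries, whose average is their 96 h effect joined to 0, and 119 had the same sign in all 4 single effects (48 higher and 71 lower). By the rule, Os10g0406350 rose by 1.07 ± 0.22 (SE, log2, limma with Benjamini-Hochberg, adjusted p = 0.00658), with single effects of 0.73 and 1.00 at 48 h and 1.37 and 1.17 at 96 h, without and with nematodes. Os04g0175300 rose by 1.02 ± 0.14 (adjusted p = 0.000165), with 1.08 and 1.51 at 48 h and 0.52 and 0.96 at 96 h. Os01g0952900 had -1.55 ± 0.28 (adjusted p = 0.00253), with -0.61 and -1.34 at 48 h and -2.45 and -1.80 at 96 h. Os02g0759400 had -1.19 ± 0.26 (adjusted p = 0.0103), with -0.54 and -0.80 at 48 h and -1.84 and -1.59 at 96 h. Both falls had under 5 normalized counts in every group at 48 h, and Os10g0406350 at 96 h. Each of these 4 kept its call with any of the 24 libraries left out. Library weights ended the calls of all 4, edgeR those of all but Os04g0175300, DESeq2 those of Os10g0406350 and Os02g0759400, and TMM factors or quantile scaling that of Os02g0759400. The filter was passed at both times by 356 loci, so most averages joined a measured and a sparsely filled time. An ID may also not measure the same gene at 48 h and 96 h, here and in the average for inoculation below. On whole reads edgeR called 3 loci and DESeq2 23, and quantile scaling moved the split to 624 higher and 463 lower.

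Averaged over spray and both times, inoculation changed 114 loci, with 74 higher and 40 lower. Of these loci, 96 were at 0 in all 48 h libraries, so that their averages joined the 96 h effect to 0. None had the same sign in all 4 single effects (0 of 114), and the rule therefore named no locus. The count of 114 became 247 without mock + Mg 96 h replicate 1, 333 without mock 96 h replicate 1 and 411 without PA + Mg 96 h replicate 2, and edgeR and DESeq2 on whole reads each called 0, with 2597 loci under an unadjusted p of 0.05 in limma.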

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

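Of the tests in this part, those on adjacent-locus levels, on the change of the roots with time and on the iron acquisition list were chosen after the result was seen, and the tests on PA effects of adjacent loci, on depth and on other splits were planned before it. The PA effect differed between inoculated and not inoculated roots for 9 loci at 48 h, by the interaction test (limma). Of 100 drawn splits of the 12 libraries, the real one included, 3 gave as many loci, with 11 as the highest of the others. The splits exchanged inoculation labels within each spray, so a random assignment of these labels was excluded at 0.05 as the whole source. They can hold part of the inoculation effect, so the test does not single out an interaction. The split with 11 calls exchanged 3 of 3 libraries in mock and 1 of 3 in PA roots.

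Reads at 24 h and 48 h lay mostly in loci whose ID number does not end in 00. Thinning the 96 h libraries to 259223 reads left at least 98% of their reads in loci ending in 00 and 16760 to 17488 loci above 0, against 4998 to 6281 at 48 h, which argues against depth. A change of the roots with time was held to a median share of reads of at least 0.1 of that at 96 h over 90 listed IDs, which were fixed before the data were examined, whereas this limit was set after. The median was 0.0527 at 24 h (bootstrap interval 0.0382 to 0.0932, 57 IDs under 0.1) and 0.00047 at 48 h (0 to 0.00963, 77 IDs under 0.1), both under that limit. The listed IDs end in 00 themselves, so a low share of reads in them restates the pattern whatever its cause. The test therefore cannot tell a change of the roots from a difference in counting, and such a change stays open. Counting on the opposite strand may account for the reads outside loci ending in 00. Levels followed the 96 h level of the more abundant locus adjacent by ID number (Spearman rho 0.238 at 24 h over 6529 loci and 0.321 at 48 h over 1564 loci). This rho was 0.013 and 0.077 for the more abundant of loci 5 to 6 places away, and -0.488 and -0.135 for the same locus. PA effects of loci called at 48 h (averaged over inoculation) followed those of the more abundant adjacent 96 h locus (r = 0.562, same sign in 98 of 120). For a locus 5 places away r was -0.04, and for the same locus 0.268 (same sign in 23 of 38). Strand and coordinates were not used.

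Iron acquisition IDs had lower values in PA-sprayed roots at 96 h, with a mean log2 fold change of -1.68 over 5 IDs and both inoculation states. The value nearest to 0 with a library left out was -1.44 (mock replicate 1), which argues against a single library as the source of this average. The comparison without nematodes alone was not tested this way. Relative to the 200 loci nearest in level to each ID, which a library factor moves alike, the mean was -1.64 (-1.36 to -1.95 with 1 ID left out), which argues against scaling as the whole cause. An effect of PA on iron status of the roots is a hypothesis that stays open, as do a shift in root makeup and a batch shared by the PA libraries, neither of which was tested.

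The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05, so only the real count and the highest of the others are given. Splits with as many loci as the real one numbered 2 for PA at 24 h (1 locus, highest other 2) and, by construction, 10 for inoculation of PA roots at 48 h, where the real count was 0 (highest other 4). They numbered 1, the real split, for PA at 48 h without (14, highest other 1) and with nematodes (113, highest other 1), and for inoculation of mock roots at 48 h (36, highest other 0). At 96 h they numbered 1 for PA without (1421, highest other 0) and with nematodes (570, highest other 78), and for inoculation of mock roots (55, highest other 3) and PA roots (86, highest other 0).

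For the interaction at 96 h the real count was 0, which all 100 drawn splits reach by construction, so this count decides nothing. The highest other split called 225, which points to a structure of the samples. It exchanged inoculation labels within each spray (2 of 3 libraries in PA and 1 of 3 in mock roots), so it held part of the inoculation effect, and a structure beyond that was not tested. For the averages over both times a random grouping was excluded at 0.05, with 1 of 100 splits for PA (1513 loci, highest other 1401) and 2 of 100 for inoculation (114 loci, highest other 294). The split with 1401 calls left the spray labels at 96 h in place and exchanged 2 of 3 libraries without and 1 of 3 with nematodes at 48 h, so it kept the PA effect of 96 h. The split with 294 calls also points to a structure of the samples. It exchanged 3 of 3 libraries in PA roots at 96 h and 2 of 3 in each other spray and time, so it held a reversed part of the inoculation effect. A part of that effect alone would not be expected to call more loci than the 114 of the real labels. What else it held was not tested.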

How the results depend on the processing

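The joint fit, the averages of 96 h alone and the fits without both inoculated 96 h replicates 3 were chosen after the data were seen; the joint fit had been the plan. The cause of the differences below was not tested, except that a minimum log2 change only removes loci. For PA at 24 h, 1 locus became 3 with a pseudocount of 5, 129 without a filter, 0 with TMM, quantile scaling or edgeR, 54 with library weights and 81 with DESeq2. A log2 change of at least 1 left 12 loci for Mg at 48 h, 54 for PA in Mg roots and 5 interactions at 48 h, and at 96 h 349 for PA, 13 for Mg, 160 for PA in Mg roots and 24 for Mg in PA roots; it left 42 and 4 for the PA and Mg averages. Without a filter there were 5 loci for Mg in PA roots and 15 interactions at 48 h. The joint fit gave 31 (PA), 41 (PA in Mg roots), 16 (Mg in PA roots) and 26 (interaction) at 48 h, and 2525 (PA), 234 (Mg), 1569 (PA in Mg roots), 1006 (Mg in PA roots) and 73 (interaction) at 96 h. edgeR called 16 and DESeq2 20 interactions at 48 h; at 96 h DESeq2 called 117 for Mg, 365 for Mg in PA roots and 9 interactions. With the libraries of the comparison alone, 96 h gave 12 for Mg, 367 for PA in Mg roots and 144 for Mg in PA roots, the last being 170 with library weights. Without both inoculated 96 h replicates 3 these were 29, 345 and 37. The PA average was 3004 with a pseudocount of 5, 1000 with TMM, 2700 with library weights, 3 with edgeR, 23 with DESeq2 and 2877 at 96 h alone, and quantile scaling gave 624 higher and 463 lower; the Mg average was 350 with a pseudocount of 5, 949 with library weights, 0 with edgeR and DESeq2, and 398 at 96 h alone.

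Of 41 list tests 21 were called (8 up, 13 down), 0 with an estimated correlation and 0 with fry's directional test. Its test of change in either direction called 2, the salicylate (adjusted p = 0.00784) and jasmonate lists (adjusted p = 0.0291) for PA at 96 h. The PA effects with and without nematodes correlated at 0.346 without a filter at 96 h, and at 48 h at 0.081 without a filter, 0.465 with a filter of 50 and 0.09 in the joint fit. Os05g0320700 reversed: its PA average was 0.20 (adjusted p = 0.539, limma) over both times and -0.34 (adjusted p = 0.0461) at 96 h alone. Of 95 results for single loci that were followed, 39 were called, and 37 uncalled values changed sign under some alternative.

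With 1 library left out, counts ranged from 0 to 72 (PA at 24 h), 4 to 24 (PA at 48 h), 15 to 38 (Mg at 48 h), 72 to 105 (PA in Mg roots at 48 h), 0 to 5 (Mg in PA roots at 48 h), 3 to 24 (interaction at 48 h), 589 to 1101 (PA at 96 h), 2 to 115 (Mg at 96 h), 243 to 604 (PA in Mg roots at 96 h), 8 to 340 (Mg in PA roots at 96 h), 0 to 2 (interaction at 96 h), 1204 to 1850 (PA average) and 83 to 411 (Mg average). Correlations ranged from 0.44 to 0.574 and 0.271 to 0.333 for PA, and from 0.185 to 0.471 and 0.018 to 0.137 for Mg, at 96 h and 48 h. List tests were not repeated this way.

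Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated between -0.298 and 0.044 at 24 h, -0.174 and 0.15 at 48 h and -0.283 and 0.371 at 96 h. Among differently numbered pairs at 96 h the range was -0.376 to 0.312, with mock + Mg replicate 1 in both extremes. Some libraries thus shared deviations across groups at 96 h. The main fits do not model these, and their source was not tested. With the replicate block, PA at 24 h had 41 loci and the Mg average 73; the other counts stayed within 1.5 times, as 1578 for PA at 96 h. Of the loci named, Os12g0555500 (PA in Mg roots at 96 h) was not called with it. Depth was lowest at 48 h, but 96 h libraries thinned to that depth had 16760 to 17488 loci above 0, against 4998 to 6281 at 48 h, so depth is not the whole limit there.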

Other observations

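The values at 96 h averaged over the other factor, their counts with libraries left out and all overlaps in this part were computed after the data were seen. Averaged over inoculation, PA changed 2877 of 20539 loci at 96 h (1406 higher and 1471 lower, limma with Benjamini-Hochberg). The count was 1890 without PA replicate 1. All 5 iron acquisition IDs fell, with a median log2 fold change of -1.59 (5 adjusted over the list alone, camera adjusted p = 1.63e-06, adjusted p = 0.313 with an estimated correlation). In the phenylpropanoid core 6 of 13 IDs fell (7 adjusted over the list alone, camera adjusted p = 0.000887), as did 6 of 11 salicylate IDs (8 lower and 1 higher adjusted over the list alone, 0.00615), 4 of 15 diterpenoid phytoalexin IDs (4 adjusted over the list alone, 0.00144) and 3 of 7 monolignol and lignin IDs (3 adjusted over the list alone, 0.012). With an estimated correlation the adjusted p was 0.323 for the diterpenoid list and 0.313 for the others. Of 7 clock IDs 2 rose (3 adjusted over the list alone, camera adjusted p = 0.00615, adjusted p = 0.313 with an estimated correlation). The directional test of fry called iron acquisition (adjusted p = 0.00445), salicylate (adjusted p = 0.0233) and the clock (adjusted p = 0.0345). For the other lists it gave at least 0.0805.

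Averaged over spray, inoculation changed 398 loci at 96 h (291 higher and 107 lower). The count was 146 without the 96 h replicates 3 of mock + Mg and PA + Mg. With 1 library left out it was 222 and 218 without mock + Mg replicate 2 and 3, 677, 190 and 196 without mock replicate 1, 2 and 3, 632 and 215 without PA + Mg replicate 2 and 3, and 206, 240 and 170 without PA replicate 1, 2 and 3. The lists that were lower after PA ranked higher after inoculation in 4 cases. They were the phenylpropanoid core (13 of 13 above 0, median 0.25, 0 passed, 2 higher adjusted over the list alone, camera adjusted p = 0.000887), iron acquisition (5 of 5 above 0, median 0.51, 1 rose, 2 adjusted over the list alone, 0.00177), salicylate (9 of 11 above 0, 1 rose, 2 adjusted over the list alone, 0.00615) and monolignol and lignin (7 of 7 above 0, 0.012). For all 4 the adjusted p was 0.313 with an estimated correlation, and 0.09 to 0.116 with the directional test of fry. Of single loci, 174 were called for both factors, where independent lists would share 55.7, and 136 of them moved the same way. Both averages came from the same 12 libraries and share each locus's spread. Lists independent among loci of similar spread and level would share 79, fewer than the 174 found. In 20 simulations without any effect 0 were shared, which decides nothing, as hardly any locus is expected to pass either test there. Whether the excess is a shared effect was not tested. Without the 96 h replicates 3 of mock + Mg and PA + Mg, 85 were called for both, against 19.2 for independent lists, and 69 moved the same way. Leaving out any 1 library but mock + Mg replicate 1 moved the overlap by over 1.5 times, to between 76 and 276.

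At 48 h, averaged over inoculation, PA changed 126 loci (57 higher and 69 lower), and averaged over spray, inoculation changed 10, all higher. PA effects without nematodes at 48 h and 96 h correlated at r = 0.145 over the 356 loci tested at both times. For loci under an unadjusted p of 0.05 at 24 h, the PA effect had the sign of the more abundant adjacent 96 h locus in 402 of 649 pairs (61.9%, r = 0.286). For a locus 5 places away r was 0.025, and for the same locus 0.134 (same sign in 132 of 234).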
